A study of Mus musculus with 2 samples.

How the data were processed

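Retinas of wild-type C57BL/6 mice at postnatal day 17 were pooled from 6 mice per group, and CD11b-positive cells were selected with magnetic beads and sequenced, per the labels' protocols. The deposited values are raw UMI counts per gene and cell barcode. The authors made these counts with Cell Ranger 3.0.2 on genome build mm10, per the submitters' processing notes, and the matrix header gives the same version. The annotation release, aligner settings and cell calling settings are not given in the sources used here. The values had not been normalised. The files hold 31053 genes. Gene positions and types came from the GENCODE annotation of build mm10, in which 30934 of the 31053 gene identifiers were found (99.6%). Where identifiers shared a symbol (36), the one with the most UMIs was used. The gene Clec7a of the disease-associated list is not among the genes of the files.

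Barcodes with at least 500 genes and at most 10% of UMIs from mitochondrial genes were kept, 9454 of 10826 in control and 6516 of 7283 in OIR. Scrublet scores gave 1 and 0 doublets at the automatic threshold, under the preset minimum of 0.5%, so the top-scoring barcodes were removed at the preset rate of 0.8% per 1000 cells: 938 control barcodes (8.66%) and 424 OIR barcodes (5.82%), of which 869 and 384 had passed the filter. The remaining 8585 and 6132 cells were clustered together without integration, since batch and group cannot be told apart with 1 library each. The steps were log normalisation, 2000 variable genes, 30 principal components, a graph of 20 neighbours and Leiden clustering at resolution 1. A cluster was named when the markers of a class, fixed before the data were examined, led it by a mean log2 fold of at least 0.5 over the other cells. At least 3 of those markers had to be detected in 10% of its cells. Clusters were left unnamed where another class had more markers, or as many above 1, among the top 10 genes, or where none of its own markers was among them and its median depth, times 3, was under that of its library. This score limit was set with the data at hand. Unnamed clusters held 93 control and 78 OIR cells (1.08% and 1.27%), and no cluster took the name of amacrine, ganglion, horizontal, endothelial, pericyte, astrocyte, dendritic, T, B, oligodendrocyte or fibroblast cells.

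Counts were summed over the cells of a class in each library and scaled to the total of the class (CPM), which were computed here from the deposited counts. The log2 ratio of OIR over control was given with an exact conditional binomial interval, CPM with an exact Poisson interval and shares with an exact Clopper-Pearson interval, all at 95%. No test was made and no p-value is given, because each group has 1 library and cells are not replicates. A count of 0 was set to 3 counts in a ratio, and the limit that a count of 0 allows was taken as 3 counts of the total, which is below the upper end of the exact two-sided interval. Genes with at least 20 CPM in 1 library were counted as 2-fold apart where the interval also excluded 0. A list's median was placed as a percentile among 10000 random lists matched on mean expression, which describes these 2 libraries. Members at or above 1.5-fold were counted in each direction. Shares of cells with a UMI were taken after each cell was thinned to 1500 UMIs, with shallower cells left out.

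The lists were homeostatic and disease-associated microglia, interferon response, mitosis, DNA synthesis, necroptosis, pyroptosis, apoptosis, hypoxia, glycolysis, oxidative phosphorylation, angiogenic factors, cytokines and chemokines, immediate early genes, MHC class I and II, complement, lipid handling and lysosome. Sex-linked, rod, mitochondrial and ribosomal genes served as checks. In microglia-like cells, mitochondrial genes took 3.28% of UMIs in control and 3.16% in OIR, and ribosomal genes 15.2% and 16.6%. The named genes were the 15 highest and 15 lowest log2 ratios among genes with at least 50 CPM, an interval excluding 0 and a CPM that, times 5, reached that in every non-myeloid class of the same library. For each list the 3 measured members with the largest ratio in either direction were added, and Ripk1, Ripk3, Mlkl and Fgf2 always. Of the genes this rule names, 2 are not reported here. For other classes with at least 200 cells in each library, the 5 highest and 5 lowest were named, with this last condition set against every other named class. The condition was applied in the library where the gene was higher. Mitochondrial, ribosomal, haemoglobin, Xist, Y-linked and unnamed predicted genes were left out, and clone names counted as unnamed.

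The interval and list steps were tested on simulated counts drawn from the microglia-like sums, with 200 of 5719 genes changed for the comparison of OIR with control. All 50 genes set 3-fold higher, all 50 set 4-fold higher and all 50 set to 0.25 of the control level were found at least 2-fold apart, as were 0 of 50 set 1.5-fold higher and 0 of 5519 unchanged genes. Intervals held the true ratio for 89.9% of unchanged genes, and for 95.8% when the totals from before the change were used for scaling, since the changed genes moved the other genes by -0.05 (log2). The intervals therefore leave out error from scaling. Of 200 random lists, 5% fell outside the central 95% of percentiles. Both simulated libraries were drawn from the same pooled profile, with counting error and the set changes only. These results therefore check the steps and give no rate of false calls between real libraries.

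Alternatives set before the data were examined covered the cell filter, doublet calls, the way cells were classed, the clustering resolution, the scaling, the weight of deep cells, the genes in the total, the CPM minimum, the thinning depth, the number of cell cycle UMIs and the subcluster resolution. TMM factors came from edgeR 4.0.16 in R 4.3.3. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.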

Results

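Single cells of mouse retina were profiled by droplet sequencing after selection with CD11b beads, which bind a surface protein of microglia and other myeloid cells. The control library came from the pooled retinas of 6 mice at postnatal day 17. The other library came from the pooled retinas of 6 mice of the same age with oxygen-induced retinopathy (OIR), a model in which pups breathe 75% oxygen from day 7 to day 12 and the retina becomes short of oxygen on return to room air. The control library held 10826 barcodes with 50081145 UMIs (unique molecular identifiers, counts of RNA molecules), and the OIR library held 7283 barcodes with 49773742 UMIs. After filtering, 8585 control cells with a median of 1648 UMIs and 6132 OIR cells with a median of 2828.5 UMIs were compared. Each group is 1 library, so no difference has a replicate check, and every interval is a 95% interval that covers counting error only. The pools also differed in sex-linked RNA. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were lower in OIR microglia-like cells (Ddx3y 25.1 in control against 7.28 CPM, the count scaled to the total of the class in its library). They were also lower in OIR rod-like, cone-like, bipolar-like and Müller glia-like cells. Xist stood at 961 and 950 CPM in microglia-like cells but was higher in OIR in those classes. It was at 1469 and 1757 CPM in rod-like, 1212 and 1840 in cone-like, 3514 and 5054 in bipolar-like and 887 and 1200 in Müller glia-like cells.

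Despite the bead selection, rod-like cells were the largest class in both libraries, with 78.7% of control cells and 60.7% of OIR cells. Microglia-like cells made up 842 of 8585 control cells (9.81%, exact interval 9.19 to 10.5) and 629 of 6132 OIR cells (10.3%, 9.51 to 11.04). Cone-like cells were 3.60% and 10.6%, bipolar-like cells 2.87% and 7.35%, and Müller glia-like cells, the radial glia of the retina, 3.05% and 6.25%. Border macrophage-like cells, marked by Pf4, Mrc1 and F13a1, were 18 control cells (0.210%) and 96 OIR cells (1.57%). Monocyte-like cells numbered 11 (0.128%) and 29 (0.473%), neutrophil-like cells 11 (0.128%) and 18 (0.294%), pigment epithelium-like cells 30 and 45, and erythroid-like cells 7 and 28. All myeloid classes together held 10.3% of control cells and 12.6% of OIR cells, and photoreceptors 82.3% and 71.3%. These are shares after a bead sort, so they describe what each library holds and not the makeup of the retina. With a stricter cell filter the microglia-like shares were 22.7% in control and 3.07% in OIR, and at a coarser clustering the OIR share was 6.59%. Naming played a part in both. Of the 252 OIR cells of a microglia-like cluster led by Mmp12, described below, 194 joined a cluster named erythroid under that filter. The filter left out 32 of them, and 7 kept the microglia name. At the coarser clustering 251 took the name of border macrophages. Many other OIR microglia-like cells were left out by the stricter filter or became unnamed under it. The shares under the stricter filter with the first names kept are given in the section on processing.

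**Figure D1:**
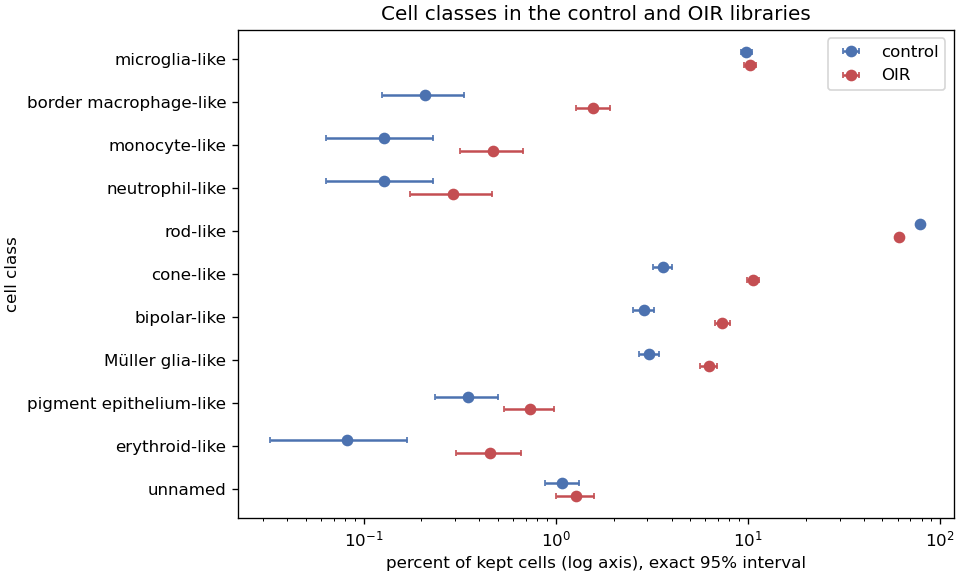
Share of kept cells in each cell class (percent, log axis) in the control and OIR libraries, with exact 95% intervals. Microglia-like cells were 9.81% and 10.3%, and rod-like cells 78.7% and 60.7%.

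The first question is how microglia differed between the retinopathy retina and the control retina. In the OIR library, microglia-like cells carried more RNA of the hypoxia, glycolysis and disease-associated gene lists and less RNA of the resting-microglia list. Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499, build mm10), the macrophage metalloelastase, stood at 0.747 CPM in control and 360 CPM in OIR, a log2 ratio of 8.91 (7.69 to 10.5). Of its OIR UMIs, 2160 lay in a cluster led by it, described below, whose name depends on the clustering. The other microglia-like clusters held 65, 1 and 1. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), which encodes osteopontin, stood at 8.07 and 1489 CPM, a log2 ratio of 7.53 (7.14 to 7.94). Hmox1 (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), the haem-degrading enzyme, stood at 80.4 and 3453 CPM, a log2 ratio of 5.42 (5.30 to 5.55). The other genes of the 15 highest were Lgals3 (5.83), Fn1 (5.82), Slc7a11 (5.38), Pf4 (5.33), Lgals1 (4.90), Ctla2a (4.31), Egln3 (4.31), Vim (4.15), Srxn1 (4.14), Anxa2 (4.03), Ube2c (3.88) and Rab7b (3.83). Tmem119 (ENSMUSG00000054675), a marker of resting microglia, was lower in OIR at 176 CPM against 615 CPM, a log2 ratio of -1.81 (-1.91 to -1.71). The lowest ratios were those of Col27a1 (-2.36) and Asb2 (-2.19), followed by Numb (-1.95), Liph (-1.93), Sgk1 (-1.92), Klf2 (-1.88), Hpgd (-1.80), Selplg (-1.79), Tsc22d3 (-1.79), Btg2 (-1.78), Arhgap5 (-1.75), Calhm2 (-1.73), Nav2 (-1.69) and Zfp710 (-1.67). Of 6076 genes with at least 20 CPM in 1 library, 307 stood at least 2-fold higher and 324 at least 2-fold lower in OIR. These numbers give the size of the difference between 2 libraries and are not a count of changed genes. Scaling by the median of ratios shifted the median of all genes by 0.12 (log2) and gave 387 higher and 222 lower, so that 63.5% of the genes apart were higher in place of 48.7%.

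Genes were then grouped by lists fixed before the data were examined. Of 16 measured genes of resting (homeostatic) microglia, 13 were at least 1.5-fold lower in OIR and 0 higher, among them Selplg and P2ry13 (-1.61), and the median log2 ratio was -1.10. Of 20 measured genes of disease-associated microglia, 14 were higher and 0 lower, with Spp1, Lgals3 and Igf1 (3.74) farthest apart and a median of 1.25. The hypoxia list, genes switched on at low oxygen, had 12 of 16 members higher and a median of 1.67, with P4ha2 at 5.001, Egln3 at 4.31 and Vegfa at 3.70. The glycolysis list had 13 of 14 members higher and a median of 1.81, led by Pgk1 (2.76), Tpi1 (2.39) and Pkm (2.14). Oxidative phosphorylation genes had a median of 0.47, with 7 of 17 higher, among them Ndufa1 (1.28), Cox5a (1.05) and Uqcrq (0.995). Of 17 mitosis genes 10 were measured, and all 10 were higher, with a median of 3.63 and Mki67 at 4.90 and Nusap1 at 3.80. Of 16 DNA synthesis genes 6 were measured, and all 6 were higher, with a median of 0.99 and Mcm6 at 1.56, Dut at 1.41 and Rrm1 at 1.17. The other members lay under 20 CPM in both libraries. A gene near 0 in control was measured only where OIR reached that minimum, which favours higher members in these lists. The median lay above at least 98.9% of 10000 random lists of the same size and expression for the disease-associated, hypoxia, glycolysis, oxidative phosphorylation, mitosis and DNA synthesis lists. The homeostatic list lay below every random list.

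Immune lists moved apart from each other. The interferon response list had 5 of 9 members higher and a median of 1.03 (percentile 100), with Cxcl10 at 1.87, Ifi27l2a at 1.55 and Ifi204 at 1.197. MHC class II genes, which present antigen, had 4 of 6 higher and a median of 2.03, led by H2-Aa (3.70), H2-Eb1 (2.91) and H2-Ab1 (2.24). MHC class I genes had 3 of 9 lower and a median of -0.21 (percentile 21.6), with Tap2 at -1.21, H2-T23 at -0.86 and Tapbp at -0.62. Cytokines and chemokines went both ways, 5 higher and 4 lower of 15, with a median of 0.04 (percentile 58.8) and Cxcl2 at 3.41 and Ccl7 at 1.96. The sign of both Cxcl2 and Cxcl10 depended on the cells used: they were at -1.04 and -2.22 within the cluster led by Tmem119 described below, at -1.02 and -1.81 without the cluster led by Mmp12, and at -0.79 and -3.28 with the stricter cell filter. Complement genes had a median of -0.05 (percentile 32.0), with C5ar1 at 0.77 and C3ar1 at 0.62. Lipid handling genes had 7 of 12 higher and a median of 0.73, led by Fabp5 (3.61), Lpl (2.25) and Plin2 (2.04). Lysosome genes had a median of 0.30 (percentile 98.7), with Ctsb at 1.17 and Ctsa at 0.78. Apoptosis genes had a median of 0.31 (percentile 94.3), with 2 higher and 2 lower of 8, Bax at 0.78, Cycs at 0.73 and Bbc3 at -1.11. Immediate early genes, which also respond to cell dissociation, were lower in 15 of 17 cases with a median of -0.98, led by Btg2, Rhob (-1.56) and Jun (-1.40).

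**Figure D2:**
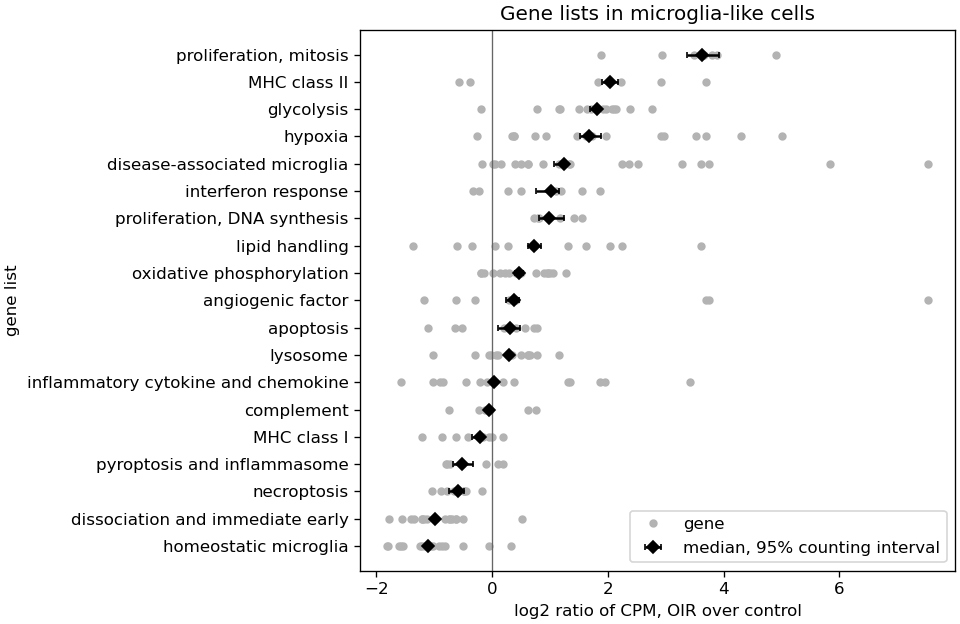
Log2 ratio of CPM (OIR over control) in microglia-like cells for each measured gene of each list (grey) and the list median with its 95% counting interval (black). The mitosis median was 3.63, the hypoxia median 1.67 and the homeostatic median -1.10.

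The size of the difference varied between clusters. Microglia-like cells fell into 4 clusters. One was led by Tmem119 and P2ry12 (653 control and 88 OIR cells) and one by Cst7, with a median of 2042.5 UMIs (163 and 249). Another was led by Mmp12 and Spp1 (23 and 252), and the last was a cycling one (3 and 40). Only the Tmem119-led cluster had microglia markers among its 10 leading genes (4), and each of the others had 0. In the cycling one the mean log2 fold of microglia markers was 0.69, against the naming limit of 0.5. A cluster made almost wholly of 1 library may be that library. The OIR cells of the Mmp12-led cluster held 108 CPM of Sall1, a transcription factor of microglia, and 11.4 CPM of Mrc1, against 15.3 and 1615 CPM in OIR border macrophage-like cells. Over all microglia-like cells, Pf4 was not the only border macrophage marker that was higher in OIR. Mrc1 stood at 0.299 and 9.87 CPM (log2 ratio 5.05, 3.13 to 8.12), Ms4a7 at 1.05 and 24.9 (4.57), Folr2 at 2.39 and 26.5 (3.47), Stab1 at 82.2 and 171 (1.05), and F13a1 had 0 and 46 UMIs; these were named after their values were seen. At a coarser clustering, 251 of these 252 cells were placed with the border macrophages, so the name of this cluster depends on the clustering. Within the Tmem119-led cluster alone, an alternative chosen after seeing the data, the medians came to 0.30 for hypoxia, 0.72 for glycolysis, 0.58 for disease-associated genes, -0.35 for homeostatic genes, -0.06 for interferon response and -0.02 for MHC class II. With the stricter cell filter, which gave most cells of the Mmp12-led cluster another name, 168 genes were higher and 133 lower and the hypoxia median was 0.27. Within the Tmem119-led cluster, Hmox1 (2.97) and Vegfa (2.34) were higher and Tmem119 (-0.51) lower. Mmp12 had 4 control and 1 OIR UMIs there (0.98, -4.64 to 4.32). The intervals of Slc7a11 (-2.57 to 2.89), Ctla2a (-0.72 to 2.52) and Egln3 (-0.26 to 2.23) also held 0 there. Those of the other genes among the 15 highest lay above 0. Within the Cst7-led cluster, Spp1 (6.17), Lgals3 (5.96) and Hmox1 (5.52) were higher and Tmem119 (-1.78) lower. Within the Mmp12-led cluster, whose control part is 23 cells, Spp1 (5.34) and Hmox1 (2.54) were higher and Tmem119 (-1.06) lower, and Mmp12 was at 6.97 (4.49 to 12.3) on 1 control UMI. The mitosis gene Ube2c was at -0.51 (-1.08 to 0.11) there, on 27 and 327 UMIs, and had 3 and 3 UMIs in the Tmem119-led cluster. Some genes of the lists changed sign with the cells used. Rrm1 was at -1.19 and Bax at -0.053 within the Tmem119-led cluster. Without the Mmp12-led cluster C3ar1 was at -0.48 and the lysosome median at -0.034, and with the stricter cell filter H2-Eb1 was at -0.52 and Srxn1 at -0.21.

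After every cell was thinned to 1500 UMIs, 2 of 784 control cells (0.255%, 0.0309 to 0.918) and 41 of 548 OIR cells (7.48%, 5.42 to 10.0) held 3 or more UMIs of mitosis genes. Thinning left out 58 control and 81 OIR microglia-like cells, whose class had median depths of 6605 and 5721 UMIs. Without thinning the shares were 0.713% and 15.7%. Thinned rod-like cells, which do not divide, gave 2 of 2979 and 0 of 1872, at unthinned median depths of 1404 and 1508 UMIs. With doublet calls kept, the cycling cells took the name of border macrophages and the OIR share came to 0.595%.

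The second question concerns RIP3, the kinase encoded by Ripk3 that drives necroptosis, a lytic form of cell death. Ripk3 (ENSMUSG00000022221, chromosome 14) was rare: 34 UMIs in control microglia-like cells (5.08 CPM, 3.52 to 7.10) and 52 in OIR (8.42 CPM, 6.29 to 11.04), a log2 ratio of 0.73 (0.08 to 1.40). Microglia-like cells held 34 of the 37 Ripk3 UMIs of the control library and 52 of the 78 of the OIR library, with 1 UMI in all control rod-like cells and 0 in OIR rod-like cells, where 3 counts, the limit that a count of 0 allows, are 0.258 CPM (exact two-sided bound 0.317). Ripk1 (ENSMUSG00000021408, chromosome 13), its binding partner, was lower in OIR at 33.3 CPM (206 UMIs) against 46.6 CPM (312 UMIs), a log2 ratio of -0.48 (-0.74 to -0.23). Mlkl (ENSMUSG00000012519, chromosome 8), the RIP3 substrate that breaks the membrane, had 1 and 5 UMIs in microglia-like cells, a ratio whose log2 interval ran from -0.72 to 8.001. OIR border macrophage-like cells held 14 Mlkl UMIs (11.9 CPM) and 15 Ripk3 UMIs (12.7 CPM), while the 18 control cells of this class had 0 of either, which allows up to 26.7 CPM by the same limit (exact bound 32.8). The necroptosis list had 5 of 9 measured members lower and 0 higher, with a median of -0.59 (percentile 0.96) and Birc3 at -1.03, Cflar at -0.87 and Casp8 at -0.77. The list does not separate genes that promote necroptosis from genes that restrain it. Its median therefore does not say whether the pathway was more or less active. Ripk3, Mlkl and Zbp1 (24 and 72 UMIs, log2 ratio 1.70) lay under the 20 CPM minimum and are not in that median; Zbp1 was named after its values were seen. Pyroptosis genes had 3 of 8 lower and a median of -0.52 (percentile 3.24), with Aim2 at -0.79, Nlrp3 at -0.78 and Gsdmd at -0.73. The interval of Ripk3 reached 0 once the microglia-like subcluster led by rod genes was left out, and within the Tmem119-led cluster Ripk1 came to -0.19 and the necroptosis median to -0.29.

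Ripk3 did not mark 1 group of microglia-like cells at this depth. A UMI was seen in 33 of 842 control cells (3.92%) and 44 of 629 OIR cells (7.00%), and after thinning to 1500 UMIs in 8 of 784 (1.02%, 0.442 to 2.001) and 4 of 548 (0.730%, 0.199 to 1.86). Thinned rod-like cells had 0 of 2979 and 0 of 1872. At other depths OIR was the higher: thinned to 1000 UMIs, 2 of 836 (0.239%, 0.0290 to 0.862) against 3 of 612 (0.490%, 0.101 to 1.43), and to 2500 UMIs, 12 of 710 (1.69%, 0.876 to 2.93) against 15 of 448 (3.35%, 1.89 to 5.46). The intervals overlap at all 3 depths, so the thinned shares give no order. When microglia-like cells were clustered again without the necroptosis and angiogenic genes, Ripk3 in OIR cells stood at 13.7, 13.3, 8.94, 2.44, 8.05 and 11.5 CPM in the 6 subclusters. The lowest, 2.44 CPM (0.296 to 8.83), was the subcluster led by rod genes, and all 6 intervals overlapped, so no Ripk3-high subcluster was detectable. Ripk1 and Ripk3 UMIs were found together in 17 control and 19 OIR cells, against 8.94 and 9.44 for independent draws; deep cells raise such counts for any pair of genes.

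**Figure D3:**
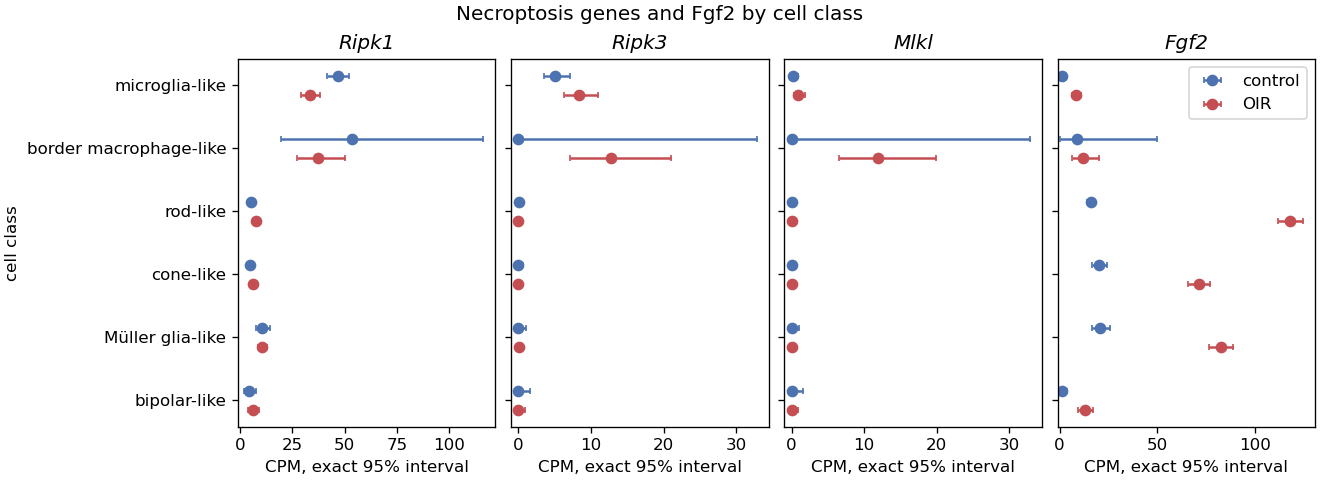
CPM of Ripk1, Ripk3, Mlkl and Fgf2 by cell class in the control and OIR libraries, with exact 95% Poisson intervals. Ripk3 was near 0 outside myeloid classes, and Fgf2 was higher in OIR rod-like cells (118 CPM) than in control ones (15.8 CPM).

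The third question concerns vessel growth factors. Fgf2 (ENSMUSG00000037225, chromosome 3), a growth factor for vessels and neurons, was mainly a photoreceptor and glial transcript. It stood at 15.8 CPM in control and 118 CPM in OIR rod-like cells, a log2 ratio of 2.90 (2.71 to 3.09), at 20.04 and 71.1 CPM in cone-like cells, and at 20.7 and 82.3 CPM in Müller glia-like cells. Photoreceptors held 403 of 501 Fgf2 UMIs in control (80.4%) and 2015 of 2861 in OIR (70.4%). Microglia-like cells held 10 and 51 Fgf2 UMIs (1.49 and 8.25 CPM), a log2 ratio of 2.47 (1.47 to 3.61). Of the 51, the rod RNA in those cells would carry 35.2 at the ratio seen in rod-like cells of the same library. The 95 OIR cells of the subcluster led by rod genes held 23 of the 51 (28.1 CPM), against 4.47 to 7.84 CPM in the other 5 subclusters. Without that subcluster 4 and 28 UMIs were left, a log2 ratio of 2.87 (1.35 to 4.84). Fgf2 UMIs were in 1 of 784 control and 2 of 548 OIR microglia-like cells after thinning to 1500 UMIs, and in 3 of 710 and 9 of 448 after thinning to 2500 UMIs. In rod-like cells thinned to 1500 UMIs the shares were 2.01% and 14.2%. The angiogenic factor list in microglia-like cells had 3 of 9 measured members higher and 2 lower, with a median of 0.38 (percentile 96.7): Spp1, Igf1 and Vegfa were higher, and Pdgfb (-1.18) and Tgfb1 (-0.62) lower, the last pair named after the values were seen. Without the Mmp12-led cluster that median was -0.36. Estimated from rod markers, rod RNA made up 3.60% of UMIs in control and 4.84% in OIR microglia-like cells. Markers of other classes were also higher in OIR microglia-like cells, named after their values were seen: of cones, Opn1sw at 7.32 and 46.6 CPM and Pde6h at 12.9 and 54.7 CPM, and of neutrophils, S100a8 with 0 and 140 UMIs and S100a9 with 0 and 67. Solved from the markers of both, cone RNA made up 0.297% and 0.846% of UMIs beside 3.36% and 4.19% of rod RNA.

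The unselected retinal cells also differed. OIR rod-like cells had more RNA of the stress regulators Cebpd (4.46) and Gadd45b (4.30), and of Pbxip1 (3.73) and E2f6 (2.94), and less of Cdr2 (-1.09), Ccpg1os (-1.06), Peli3 (-1.02), Kcnj14 (-1.02) and Tmem35a (-0.95), all as log2 ratios. OIR cone-like cells had more Gadd45b (3.55), Lgr5 (1.96), Hmgb2 (1.86), Fgf2 (1.83) and Snhg9 (1.499), and less Cdr2 (-1.04), Kcnj14 (-0.98), Mns1 (-0.84), Ccpg1os (-0.82) and Pdzph1 (-0.81). OIR bipolar-like cells had more Cox4i2 (4.32), Matk (4.09), Hk2 (3.32), Hmgb2 (2.87) and Selenbp1 (2.86), and less Ddit4l (-1.86), Nwd2 (-1.70), Tagln3 (-1.40), Cck (-1.36) and Smim18 (-1.35). OIR Müller glia-like cells had 481 UMIs of Serpina3n, a gene of reactive glia, against 0 in control, a log2 ratio of 6.135 with the 0 set to 3 counts (lower bound 5.83). They also had more Lcn2 (5.66), Adm (4.57), Akap12 (4.44) and Ndufa4l2 (4.05), and less Kcne1l (-2.22), Hist1h4i (-2.06), Flrt2 (-1.97), Slitrk2 (-1.91) and Hmx1 (-1.87). At least 2-fold apart were 109 higher and 15 lower genes in rod-like cells, 52 and 15 in cone-like cells, 104 and 64 in bipolar-like cells and 141 and 288 in Müller glia-like cells, again as a size between 2 libraries. The bipolar-like cells came from a cluster of 182 control and 224 OIR cells and one of 64 and 227, and the Müller glia-like cells from one of 246 and 292 and a deep one of 16 and 91. Hk2 was at 3.34 and 3.10 in these bipolar-like clusters. In the first of them Ddit4l was at -1.56, Nwd2 at -1.41, Tagln3 at -1.20, Cck at -1.09 and Smim18 at -1.12. In the other, Ddit4l, Nwd2 and Cck had only 2, 1 and 0 control UMIs. In the larger Müller glia-like cluster Lcn2 was at 7.20, Akap12 at 5.94, Adm at 4.63, Ndufa4l2 at 4.15 and Kcne1l at -2.18. In the deep one, with few control cells, they were at 0.82 (-0.53 to 2.53), 2.21, 5.41, 5.32 and -0.86. Within the main rod-like cluster of 4867 control and 963 OIR cells, Cebpd was 3.94 and Fgf2 1.49, and within a cluster of 80 control and 1980 OIR cells Cebpd was -0.07 and Fgf2 0.35.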

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

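The test on haemoglobin was chosen only after the result was seen. In the OIR library, 56 of 629 microglia-like cells (8.90%, exact interval 6.80 to 11.4) held 10 or more haemoglobin UMIs, against 0 of 842 control cells, although haemoglobin belongs to no comparison of the report. Low counts were spread over the other classes too. At least 1 haemoglobin UMI was in 56.8% of OIR and 4.39% of control microglia-like cells. In the same order, the shares were 44.1% and 2.90% in rod-like and 59.9% and 9.39% in cone-like cells. They were 55.4% and 5.69% in bipolar-like and 62.1% and 6.11% in Müller glia-like cells. If free haemoglobin RNA or chance doublets caused the cells with 10 or more UMIs, the other 4 classes of the same library should show a like share of such cells. The rod-like, cone-like, bipolar-like and Müller glia-like cells showed 10 of 5209 (0.192%, 0.0921 to 0.353). Within the OIR microglia-like cells, the share with 10 or more was 15.1% (38 of 252) in the Mmp12-led cluster and 6.43% (16 of 249) in the Cst7-led one. It was 2.5% (1 of 40) in the cycling cluster and 1.14% (1 of 88) in the Tmem119-led cluster. The share was 6.90% (2 of 29) in OIR monocyte-like, 11.1% (2 of 18) in neutrophil-like and 1.04% (1 of 96) in border macrophage-like cells. Among OIR microglia-like cells, 5 held 65.5% of the haemoglobin UMIs. Uptake of red blood cells by microglia, red cells stuck to CD11b-positive cells during the sort, and bleeding in the OIR pool stay open, and none of these was tested.

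Border macrophage-like cells made up 1.57% of OIR cells (96 of 6132) against 0.210% of control cells (18 of 8585), a signal above the control library in cells outside the microglia comparison. Monocyte-like cells made up 0.473% of OIR cells (29 of 6132) against 0.128% of control cells (11 of 8585), also above the control library.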

How the results depend on the processing

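The settings that leave out a cluster, subcluster or haemoglobin-rich cells, that take away free rod RNA or that keep the first class names under the stricter filter were chosen only after the results were seen; the others were set before. No paired analysis was possible because each group is 1 library and no test was made. Among the results that answer a comparison, 137 values under an alternative stayed within the counting interval (or 1.5 times the count) and 43 did not. Among the other results these were 1113 and 532, with 18 changes of sign, counted for genes whose interval excluded 0 and for lists outside the central 95% of random lists. Of the lists inside it, the angiogenic factor, apoptosis, cytokine and complement medians also changed sign under some settings. The log2 ratios of Ripk3, Mlkl and Fgf2 in microglia-like cells stayed within their intervals under every setting run. Unless stated, the cause was not tested. Ripk3, Mlkl and Fgf2 rest on few UMIs, which widens their intervals.

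Under the looser cell filter the control microglia-like share was 11.5%, the angiogenic median 0.50 and the OIR cell cycle share 4.12%. Under the stricter filter the microglia-like shares were 22.7% in control and 3.07% in OIR, 168 genes were higher and 133 lower, the medians were -0.26 for necroptosis, 0.27 for hypoxia and 0.11 for angiogenic factors, and the cell cycle shares were 0% and 0%. The sign changed there for Srxn1 (-0.21), Cxcl10 (-3.28), Rrm1 (-1.52), Bax (-0.12), Cxcl2 (-0.79), H2-Eb1 (-0.52), C3ar1 (-0.074) and the interferon median (-0.10). Where the cells went shows both naming and filtering at work. Of the 252 OIR cells of the Mmp12-led cluster, 194 joined a cluster that the naming rule called erythroid. No erythroid marker was among its leading genes. Of the 249 OIR cells of the Cst7-led cluster, the filter left out 176, 70 became unnamed and 1 stayed microglia-like. Of the 40 OIR cells of the cycling cluster, 22 were left out and 16 became unnamed. With the first class names kept under that filter, the shares were 23.8% and 15.3%, and the hypoxia median was 1.80.

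With doublet calls kept, the OIR share was 8.92%, the hypoxia median 1.496 and the cell cycle shares 0% and 0.595%. Classing each cell by its own markers gave shares of 9.16% and 8.22%. At clustering resolution 0.5 the OIR share was 6.59% and 594 genes were lower. Median of ratios scaling gave medians of -0.47 for necroptosis and 0.50 for angiogenic factors. With every cell weighing the same, the medians were -0.82 for necroptosis and 1.41 for hypoxia. With no CPM minimum 1115 genes were higher and 687 lower, and with at least 100 CPM 113 and 126, where other genes are tested. Without thinning the OIR cell cycle share was 15.7%, since deep cells hold more UMIs.

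Without the rod-led subcluster the hypoxia median was 1.99, and with free rod RNA taken away 1.89. In only the cluster led by microglia markers, 127 genes were higher and 113 lower, Ripk1 was -0.19, and the medians were -0.29 for necroptosis, 0.30 for hypoxia and 0.014 for angiogenic factors. The sign changed there for Cxcl10 (-2.22), Rrm1 (-1.19), Bax (-0.053), Cxcl2 (-1.04), the interferon median (-0.063) and the MHC class II median (-0.017). Without the Mmp12-led cluster 547 genes were lower and the medians were -0.78 for necroptosis, 0.68 for hypoxia and -0.36 for angiogenic factors. The sign changed there for the angiogenic factor median, Cxcl10 (-1.81), Cxcl2 (-1.02), C3ar1 (-0.48) and the lysosome median (-0.034).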

Other observations

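The tests on Fgf2, the test with monocyte markers and the test within the other clusters were chosen only after the result was seen. The hypoxia and glycolysis lists were also placed in other retinal classes of the OIR library. In bipolar-like cells the hypoxia median was 0.78 and the glycolysis median 0.61, and in Müller glia-like cells 0.59 and 0.58, each above all 10000 random lists. In rod-like cells they were 0.05 (percentile 63.5) and 0.07 (percentile 77.7), and in cone-like cells -0.10 (percentile 11.8) and 0.22 (percentile 99.97). Differences between classes were not tested.

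Other lists fixed in advance also moved outside microglia. In bipolar-like cells, 3 of 5 measured MHC class I genes were higher, with a median of 2.58. The angiogenic factor list had a median of 1.85 in rod-like cells (2 of 3 measured members higher, percentile 99.9), 0.98 in cone-like cells (2 of 3), 0.36 in bipolar-like cells (1 of 3) and 0.83 in Müller glia-like cells (3 of 5, 1 lower). The disease-associated list had 4 of 8 higher in rod-like cells, with a median of 0.69 (percentile 100). The condition against free RNA was applied to named genes only and not to list members. RNA carried over from other classes, such as from microglia-like into rod-like cells, may therefore enter these medians and was not tested. In Müller glia-like cells the interferon response list had 2 of 5 higher and a median of 0.55. In rod-like cells, 5 of 17 immediate early genes were higher, with a median of 0.26, and in bipolar-like cells 4 of 13, with a median of 0.50 (percentile 100). The same list was at -0.06 in cone-like cells, at -0.20 in Müller glia-like cells (percentile 0.585) and at -0.98 in OIR microglia-like cells.

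Fgf2 was higher in OIR microglia-like cells. The rod RNA in these cells would carry 35.2 of the 51 UMIs (69.1%) at the mean ratio of rod-like cells, and the observed count was 1.45 times that (1.08 to 1.90). At the ratio of all kept cells, and with carried rod and cone RNA summed, it was 1.49 times the carried count (1.11 to 1.96 in both). In control the observed 10 UMIs were 2.62 (1.26 to 4.82), 2.09 (1.001 to 3.84) and 2.52 (1.21 to 4.64) times the carried count, in the same order. Free RNA of those mean makeups thus leaves some UMIs over in both libraries, although 23 of the 51 OIR UMIs lay in the subcluster led by rod genes. The intervals leave out error in the carried count. At the ratio of the rod-like cluster richest in Fgf2, the observed OIR count was 0.756 of the carried count (0.563 to 0.995). In control it was 0.214 (0.102 to 0.393), 10 UMIs against 46.8 carried. RNA from those rods as the one source thus overshoots in control. In OIR the upper end lay just under 1 with error in the carried count left out, so an overshoot there stays undecided. Expression by microglia stays open, as does free RNA with a larger part from those rods in OIR than in control, since that cluster holds 80 control and 1980 OIR cells.

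The hypoxia and glycolysis lists were higher in OIR microglia-like cells, with a median of 1.71 over 30 genes. In rod-like cells the hypoxia and glycolysis medians were only 0.05 and 0.07. Rod RNA made up 3.60% of control and 4.84% of OIR microglia-like UMIs. These values argue against rod RNA as the cause. With free rod RNA taken away the median was 1.95 (1.92 to 2.08), a step that at such values could hardly have lowered it. Monocyte markers stood at a median of 0.00381 of their level in monocyte-like cells. That argues against cells with monocyte-level markers making up a large part of the class. The naming of clusters by markers set part of this result. Cells derived from monocytes but without these markers would not be seen and stay open. Within the cluster with most control cells the median was 0.66 (0.47 to 0.73), an interval that spans the 1.5-fold bound set for that test, so the mix of clusters stays open there. That median pools both lists. The separate medians given above for this Tmem119-led cluster lay under the bound for hypoxia and above it for glycolysis. In the other clusters with at least 20 cells in each library it was 1.09 (1.02 to 1.41) and 1.16 (1.02 to 1.42), which argues against another mix of clusters as the whole cause, and part of the difference may still come from the mix. A response of microglia to retinopathy and a batch difference between the 2 libraries cannot be told apart with 1 library each.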
